A study of Mus musculus with 32 samples.

How the data were processed

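RNA was taken from brain tissue homogenates of 32 mice with human APOE3 or APOE4 in place of mouse Apoe. The mice were about 10.5 months old at the start and 13.2 months at the end of 12 weeks of daily D4F or PBS. According to the labels, total RNA was extracted with a kit for fatty and fibrous tissue, messenger RNA libraries that keep the strand were made, and paired reads of 150 bases were sequenced to about 20 M per sample. The deposited values are raw counts per gene name, which the authors made by trimming with Trimmomatic, aligning with HISAT2 to the mouse build GRCm38 and counting with featureCounts. The tool versions, the annotation, the strand setting and whether reads or read pairs were counted are not given in the sources used here. The mouse build alone was named, so reads from the human APOE sequence were not counted under a name of their own.

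The count table held 33 columns, a gene name and 32 libraries, and 57010 genes. Of these, 150 repeated a name already present and were kept as separate entries. It was checked that every value was a whole number and that column totals differed between libraries, as raw counts do. Each column was matched to its group by its label. Coordinates, gene type, length and GC content came from GENCODE M21 on GRCm38, matched by symbol, and 19223 of the tested genes (94.7%) had a GC value. Genes with near-identical copies or pseudogenes share reads, so their separate values are uncertain.

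Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 8 groups with a minimum count of 10 and a minimum total of 15, which left 20298. Library sizes were scaled by TMM, dispersions were estimated, and quasi-likelihood models were fitted with robust settings and 1 coefficient per group, so that every comparison was a contrast tested by the quasi-likelihood F test. The reported comparisons average the 2 sexes, apart from those within 1 sex. P-values were adjusted by the method of Benjamini and Hochberg over all genes tested, a gene was called at an adjusted p below 0.05, and all tests were two-sided. The p-values measure the spread between mice. Counts per M are TMM-scaled, with a prior count of 2 on the log scale, and errors are SD over mice unless named SE, the standard error of a log2 fold change.

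A total of 15 comparisons was made: genotype in vehicle mice, D4F in E4/4, D4F in E3/3, their interaction, genotype under D4F, treated E4/4 against vehicle E3/3, sex in vehicle mice, and 8 within a sex or for interactions with sex. Both main effects that the reversal question needs share the E4/4 vehicle libraries. The share of genes with opposite signs was therefore set beside simulations without a genotype or a D4F effect, where as many genes with the smallest p were taken. It was also set beside 36 divisions of the E4/4 vehicle libraries between the comparisons.

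The comparisons, the gene lists, the filters, the tests, the alternatives to be tried and the rule for naming genes were chosen before the data were examined. The rule named, for each of the first 7 comparisons, the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among called genes with a mean log2 CPM of at least 1. It added up to 4 members with the smallest p of each called list, 12 fixed genes in the genotype and D4F comparisons, the 5 genes with the smallest p each way where fewer than 10 genes were called, the 3 genes with the smallest adjusted p within a sex, and the sex-linked genes as a check of the labels. Some genes that the rule picks are left out of the text.

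Gene groups were tested with 45 lists covering lipid and energy metabolism, stress responses, brain cell types and regions, blood, synapses, hormones and the chromosomal neighbourhood of Apoe. The lists held 1204 symbols, of which 1 was not found, 3 were found under another name and 64 were in 2 or more lists. Camera compared each list with all other genes with a preset correlation of 0.01 between genes, and a list was called at an adjusted p below 0.05 over the lists. It was repeated with a correlation estimated from the data. Fry tested whether the genes of a list moved, on balance, 1 way, and does not compare the list with other genes. Lists needed at least 5 tested members.

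The libraries held 17.77 to 45.06 M counts. A gap in the totals divided them at 26 M (mega) counts into a lower and a higher depth class. The sensitivity of the model was tested on simulated data, with libraries drawn at the observed totals and dispersions. The 200 changed genes were drawn from those with a mean log2 CPM of at least 1, and no differences by depth class or GC content were simulated. Measures of library composition were compared between groups of 8 with exact two-sided permutation tests over 12870 regroupings. For each model result, up to 100 other splits of the same libraries into groups of the same size were fitted.

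Alternatives fixed at that time were DESeq2 size factors, DESeq2 1.42.0 with its Wald test, limma 3.58.1 voom with sample quality weights, no filter on low counts, a mean CPM of at least 1, a fit on only the groups compared, replicate number as a block, sex as an additive term, 2 surrogate variables from sva 3.50.0, fits without robust settings, and leaving out each library in turn. Alternatives added after the data were seen were the depth class as a covariate, offsets for GC content and gene length fitted with mgcv 1.9.3, both of these together, leaving out the 11 libraries of lower depth, Rn18s-rs5 as a covariate, and thinning every library to the smallest total. Splicing, variants and the human APOE transcript were not analysed here, since the values are counts per gene.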

Results

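Gene expression was measured by RNA sequencing in brain tissue from 32 mice in which the mouse Apoe gene is replaced by the human APOE3 or APOE4 coding sequence on both alleles (E3/3 and E4/4). APOE is the main carrier of cholesterol between brain cells, and APOE4 is the form that raises the risk of Alzheimer's disease. Female and male mice of each genotype received either D4F, a peptide that mimics the apolipoprotein A-I of high-density lipoprotein, or phosphate-buffered saline (PBS, called vehicle here) each day for 12 weeks. This gave 8 groups of 4 mice, and 8 mice in each combination of genotype and treatment. The libraries held 17.77 to 45.06 M counts each (M, mega), and 20298 genes had enough counts to be tested. Total counts averaged 24.8 ± 6.44 M in E3/3 vehicle, 29.7 ± 6.39 M in E3/3 D4F, 34.7 ± 7.99 M in E4/4 vehicle and 32.4 ± 9.24 M in E4/4 D4F (SD, n = 8 each). The libraries fell into a lower class of 11, from 17.77 to 23.58 M counts, and a higher class of 21, from 28.95 to 45.06 M. The lower class held 6 of the 8 E3/3 vehicle libraries, 2 of the E3/3 D4F, 1 of the E4/4 vehicle and 2 of the E4/4 D4F libraries, so depth and group overlap in every comparison with E3/3 vehicle. Total counts in E4/4 vehicle and E3/3 vehicle differed with p = 0.0213 in an exact two-sided permutation test (n = 8 and 8), or 0.106 after adjustment over 20 such tests. The slope of log counts on GC content averaged −0.00671 in E4/4 vehicle and 0.0130 in E3/3 vehicle. This difference had p = 0.000622 in an exact two-sided permutation test (n = 8 and 8), adjusted p = 0.00311 over 15 tests. For D4F in E3/3 the slope had p = 0.0345 in the exact permutation test (n = 8 and 8), adjusted p = 0.0575. Across genes, log2 change correlated with GC content at −0.440 for genotype, −0.397 for D4F in E3/3 and −0.0570 for D4F in E4/4.

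**Figure D1:**
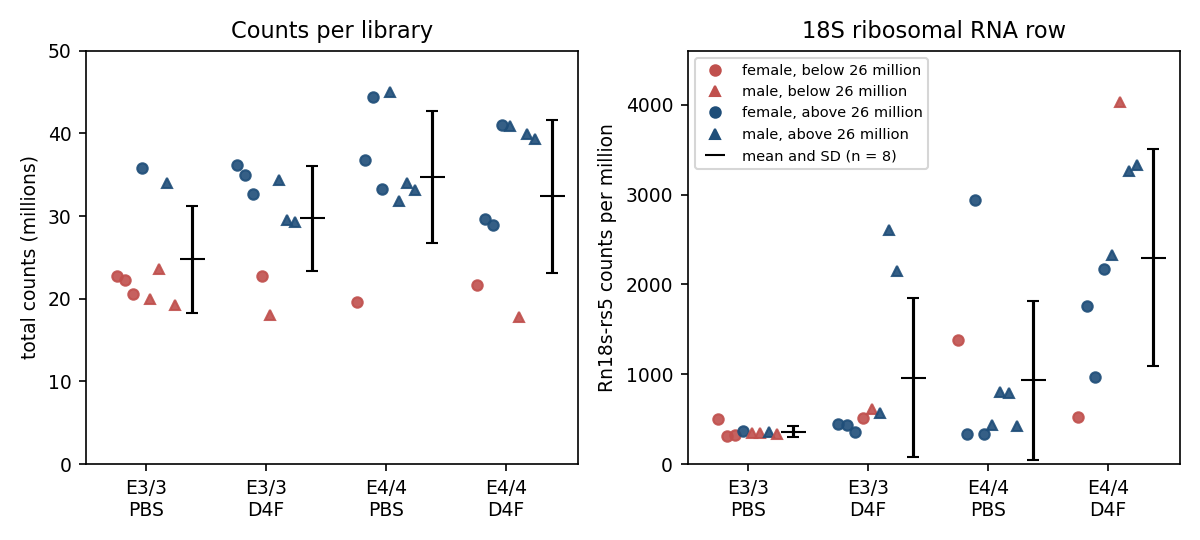
Total counts in M (mega) and counts per M of Rn18s-rs5, a ribosomal RNA gene, in each of the 32 libraries by genotype and treatment. Of the 11 libraries below 26 M counts, 6 belong to E3/3 vehicle, and mean Rn18s-rs5 runs from 362 counts per M in E3/3 vehicle to 2298 in E4/4 D4F.

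The first comparison asked how the brains of E4/4 mice differed from those of E3/3 mice without treatment. Among the genes that passed, presynaptic and glycolytic genes were mostly lower in E4/4 vehicle mice, and Abca1 and 9 of 28 myelin genes were higher, but no gene list was called when the correlation between genes was estimated. Abca1, the exporter that loads cellular cholesterol onto APOE (chromosome 4, 53030787 to 53159895 in GRCm38), averaged 22.5 ± 3.14 counts per M (CPM) in E3/3 vehicle and 35.6 ± 4.78 CPM in E4/4 vehicle (SD, n = 8 each), a 1.58-fold difference (log2 0.66, SE 0.0783, adjusted p = 1.72e-05, edgeR). Syn1, which tethers synaptic vesicles (chromosome X, 20860511 to 20921004), fell from 803 ± 147 to 500 ± 65.2 CPM (SD, n = 8 each), a log2 change of −0.68 (SE 0.11, edgeR adjusted p = 0.000139). Aspa, an oligodendrocyte enzyme that breaks down N-acetylaspartate (chromosome 11, 73304992 to 73329596), rose from 16.8 ± 3.33 to 25.5 ± 2.63 CPM (SD, n = 8 each), a log2 change of 0.59 (edgeR adjusted p = 0.00011). Across all genes, 4137 passed an adjusted p of 0.05, 2007 higher and 2130 lower in E4/4. Most differences were small: the median absolute log2 change of these genes was 0.32, 554 exceeded 1.5-fold and 166 exceeded 2-fold.

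**Figure D2:**
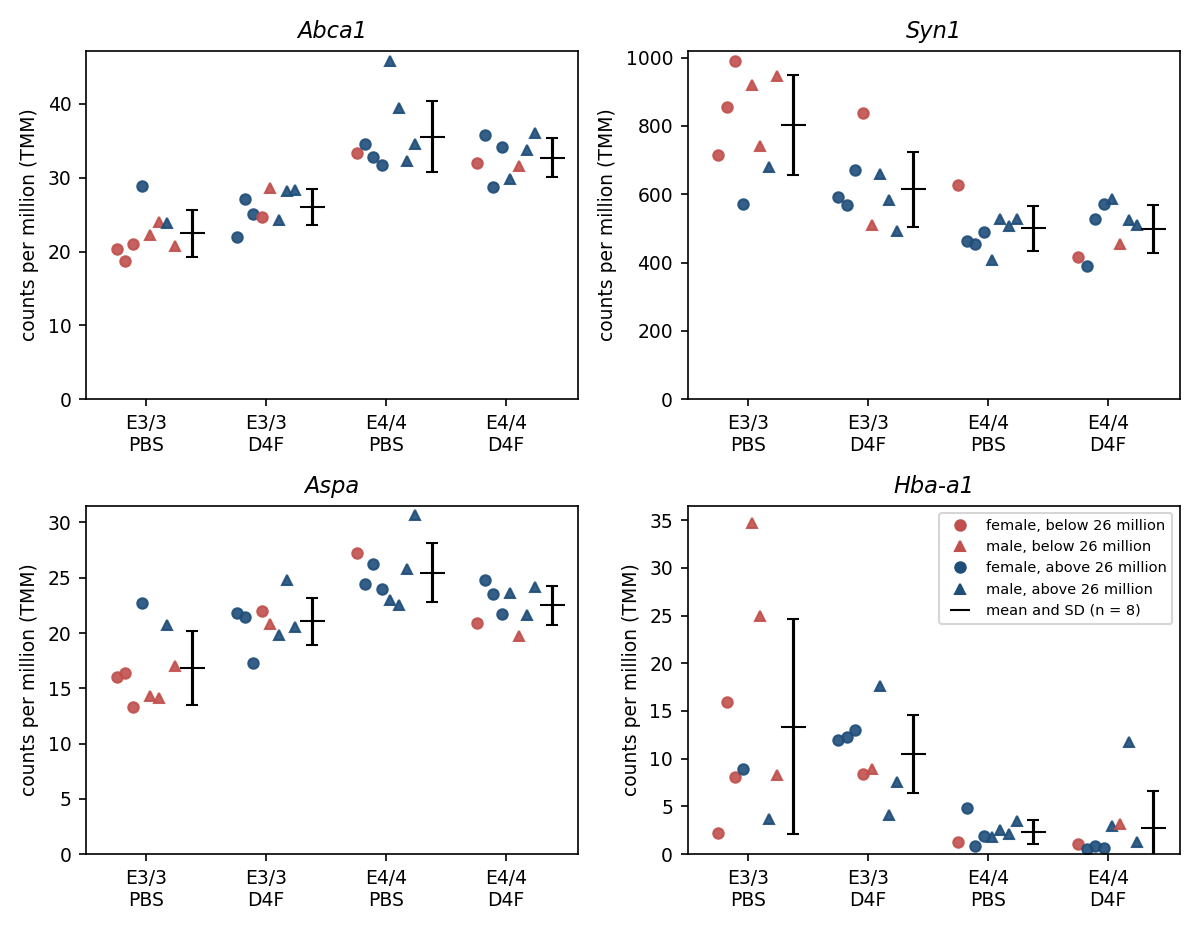
Counts per M of Abca1, Syn1, Aspa and Hba-a1 in each library by genotype and treatment, with the mean and SD of the 8 mice in each, where marker shape gives sex and colour gives whether the library lies below or above 26 M counts. Mean Abca1 is 22.5 in E3/3 vehicle and 35.6 in E4/4 vehicle, mean Syn1 is 803 and 500, mean Aspa is 16.8 and 25.5, and mean Hba-a1, in which near-identical copies share reads, is 13.4 and 2.34.

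Of 45 gene lists fixed beforehand, 11 stood apart from the other genes by camera with its preset correlation, 3 higher and 8 lower in E4/4. None kept that call when the correlation between genes was estimated, and fry called 6. In the synaptic vesicle and presynaptic list, 16 of 30 genes fell and none rose. The median log2 change was −0.27 (camera adjusted p = 5.46e-10, adjusted p = 0.398 with an estimated correlation), with 18 lower adjusted over the list alone. They included Sncb (−0.59), Syp (−0.46) and Vamp2 (−0.43), which encode a synuclein and a pair of vesicle membrane proteins. The postsynaptic list was mixed, with 12 of 30 genes lower and 4 higher. The median was −0.18 (camera adjusted p = 0.000417, adjusted p = 0.492 with an estimated correlation), with 13 lower and 5 higher adjusted over the list alone. Its lower members held the scaffolds Shank1 (−0.87), Dlgap3 (−0.70) and Dlg4 (−0.49) and the NMDA receptor subunit Grin1 (−0.50). Markers of cortical and hippocampal excitatory neurons were lower for 10 of 24 genes, among them the calmodulin-binding Nrgn (−0.88), the vesicular glutamate transporter Slc17a7 (−0.59) and the kinase Camk2a (−0.55). The median was −0.42 (camera adjusted p = 0.000342, adjusted p = 0.398 with an estimated correlation), with 13 lower and 2 higher adjusted over the list alone. In glycolysis, 14 of 24 genes fell and 1 rose, including hexokinase Hk1 (−0.56), Gapdh (−0.45) and the pyruvate dehydrogenase kinase Pdk2 (−0.42). The median was −0.20 (camera adjusted p = 1.93e-06, adjusted p = 0.311 with an estimated correlation), with 16 lower and 1 higher adjusted over the list alone. Of 30 genes of the unfolded protein and heat shock response, 11 fell and none rose, such as the stress-induced Chac1 (−0.49), the calcium-binding chaperone Calr (−0.40) and Hspa8 (−0.28). The median was −0.15 (camera adjusted p = 0.0005, adjusted p = 0.398 with an estimated correlation), with 12 lower and 1 higher adjusted over the list alone. Of the genes named in this paragraph, Nrgn (−0.719, adjusted p = 0.0721), Hspa8 (−0.207, 0.0589) and Chac1 (−0.447, 0.0559) lost their calls with depth class in the model. Chac1 also did with GC and length trends removed (−0.346, adjusted p = 0.0741). The higher-depth libraries alone hold 1 female and 1 male E3/3 vehicle library. There the genes named in this paragraph kept their direction, from −0.808 for Nrgn to −0.0759 for Calr and −0.0258 for Gapdh.

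Myelin genes rose in 9 of 28 cases and fell in none. The median was 0.20 (camera adjusted p = 0.000417, adjusted p = 0.917 with an estimated correlation), with 11 higher adjusted over the list alone. Besides Aspa they included Ugt8a (0.57), which makes galactosylceramide, and Tspan2 (0.41). Of 20 cholesterol synthesis genes 3 fell: the mevalonate enzymes Pmvk (−0.41) and Mvk (−0.35), and squalene synthase Fdft1 (−0.23). Fdft1 lost its call with depth class in the model (−0.213, adjusted p = 0.0765) and with GC and length trends removed (−0.166, adjusted p = 0.0635). The list's median was −0.09 (camera adjusted p = 0.0413, adjusted p = 0.917 with an estimated correlation), with 3 lower adjusted over the list alone. Mitochondrially encoded genes had a median of 0.46 with 3 of 15 higher, mt-Nd3 (0.77), mt-Co3 (0.62) and mt-Rnr2 (0.48), but the median was −0.05 once trends with GC content and gene length were removed, and none of the 3 passed then (adjusted p from 0.103 to 0.22). With depth class in the model mt-Rnr2 (0.503) passed, and mt-Nd3 (0.746, adjusted p = 0.054) and mt-Co3 (0.461, adjusted p = 0.258) did not. The camera adjusted p was 0.0191 (adjusted p = 0.917 with an estimated correlation), with 8 higher adjusted over the list alone. Choroid plexus markers had a median of 0.93 with 2 of 23 higher, the water channel Aqp1 (1.91, SE 0.551) and the tight junction protein Cldn1 (0.95), and the same number adjusted over the list alone. With depth class in the model the median was 0.36 and neither gene passed (Aqp1 1.05, adjusted p = 0.264, and Cldn1 0.582, adjusted p = 0.174). The camera adjusted p was 0.00557 (adjusted p = 0.917 with an estimated correlation). In the blood list 5 of 13 genes fell. The median was −0.15 and the mean −0.70 (camera adjusted p = 0.0358, adjusted p = 0.917 with an estimated correlation), with 7 lower and 1 higher adjusted over the list alone. They held the haem synthesis enzyme Alas2 (−2.37) and the haemoglobin genes Hba-a2 (−2.52), Hbb-bs (−2.51) and Hba-a1 (−2.41), whose near-identical copies share reads, so their separate values are uncertain. Genes that neighbour Apoe on chromosome 7 and lie near the edited locus were lower for 12 of 31 and higher for none, such as Ppp1r37 (−0.53), Mark4 (−0.34) and Rtn2 (−0.26). Mark4 was −0.111 with GC and length trends removed (adjusted p = 0.156), and Rtn2 −0.166 with depth class in the model (adjusted p = 0.0939). The median was −0.17 (camera adjusted p = 0.000342, adjusted p = 0.398 with an estimated correlation), with 14 lower adjusted over the list alone.

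**Figure D3:**
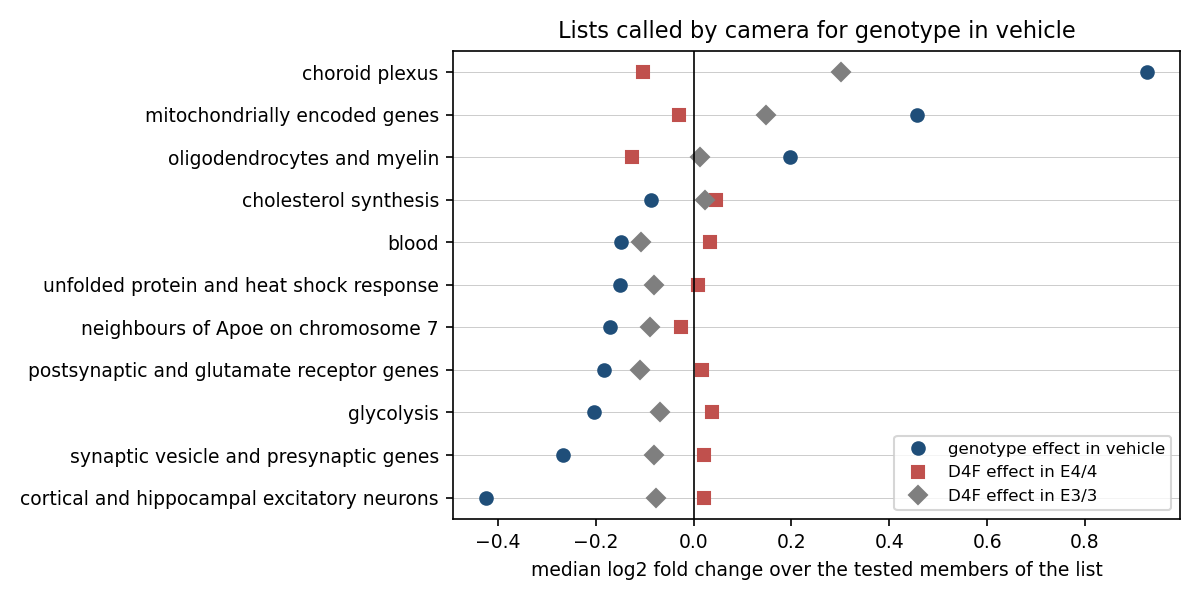
Median log2 fold change of the 11 gene lists called by camera in the genotype comparison, shown for that comparison and for D4F against vehicle in E4/4 and in E3/3. Medians for genotype run from −0.42 for cortical and hippocampal excitatory neurons to 0.93 for choroid plexus, and that of mitochondrially encoded genes (0.46) is −0.05 after removal of GC and length trends.

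By size of change, the largest increases outside those lists were in the metalloprotease Adamts19 (log2 2.68), the small nuclear RNA gene Rn7sk (2.32), the synaptic Doc2g (1.64), the transcription factors Sp8 (1.52) and Sp7 (1.43), the Wnt receptor partner Lgr5 (1.48), Trh (1.47), the precursor of thyrotropin-releasing hormone, and Fabp7 (1.38), a fatty acid binding protein of radial glia and astrocytes. Of these, Trh and Fabp7 kept an adjusted p below 0.05 in all 32 fits that left out 1 library, Rn7sk and Sp7 in 31, Lgr5 in 26, Adamts19 in 25, Doc2g in 23 and Sp8 in 13. With depth class in the model Fabp7 passed (1.28, adjusted p = 0.0486) and the other 7 did not (adjusted p from 0.069 for Rn7sk to 0.317 for Sp8). The 7 were then at 2.07 (Adamts19), 2.28 (Rn7sk), 1.26 (Doc2g), 1.12 (Sp8), 1.27 (Sp7), 1.15 (Lgr5) and 1.35 (Trh). Sp8 (1.55) and Lgr5 (1.39) also lost their calls with GC and length trends removed (adjusted p = 0.0562 and 0.0531). In the higher-depth libraries alone, with 1 female and 1 male E3/3 vehicle library, these increases ran from 1.87 for Fabp7 to 5.45 for Adamts19. The largest decreases outside the blood genes were in Gipc3 (−1.29), the neuronal small RNA gene Bc1 (−1.17), Krt80 (−1.13), Arhgap25 (−0.93), the cortical projection neuron factor Fezf2 (−0.92) and 2 predicted genes, Gm15542 (−1.06) and Gm9118 (−0.93), which may share reads with related copies. Gipc3, Gm15542 and Gm9118 kept their calls in all 32 such fits, Arhgap25 in 24, Krt80 in 23, Bc1 in 22 and Fezf2 in 10. With depth class in the model Gipc3 (−1.22) and Gm15542 (−0.726) passed. Gm9118 (−0.709, adjusted p = 0.0965), Krt80 (−1.18, 0.102), Arhgap25 (−0.858, 0.109), Fezf2 (−0.887, 0.153) and Bc1 (−0.275, 0.737) did not. In the higher-depth libraries alone, with 1 female and 1 male E3/3 vehicle library, Gm15542 was −0.218, Gm9118 −0.129 and Bc1 1.03. Gipc3 was −1.34 there, Krt80 −1.33, Arhgap25 −1.22 and Fezf2 −0.964. Krt80 (−1.05) and Fezf2 (−0.801) also lost their calls with GC and length trends removed (adjusted p = 0.0685 and 0.104). Xist, which coats the inactive X chromosome, also passed (2.22), but in the average over sexes this value rests on traces of at most 140 counts in male libraries. With depth class in the model Xist was 2.04 and did not pass (adjusted p = 0.0736). Among 12 lipid, glial and neuronal genes fixed beforehand, Abca1 was higher and the APOE receptor Lrp1 was lower (−0.19, adjusted p = 0.0238). Lrp1 lost its call with GC and length trends removed (−0.0436, adjusted p = 0.551) and with depth class in the model (−0.179, adjusted p = 0.117), and kept it in 9 of 16 alternative settings and in 24 of 32 fits that left out 1 library. Neither the astrocyte filament gene Gfap (0.24), the microglial receptor Trem2 (0.05), Aif1 (0.10), Mbp (0.10), the exporter Abcg1 (0.02), Clu (−0.13) nor Snap25 (−0.16) passed, with adjusted p = 0.209 for Gfap. Mouse Apoe itself had 2.69 ± 0.316 CPM in E3/3 vehicle and 2.73 ± 0.524 CPM in E4/4 vehicle (SD, n = 8 each), with a log2 change of 0.03. The human coding sequence replaces it in these mice, so this is no readout of the human gene.

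The number of genes called varied with the setting for depth. With depth class in the model 1286 genes passed, 1273 of them among the 4137. With every library thinned to the smallest total 3706 passed, 3458 of them among the 4137. In the 21 higher-depth libraries alone E3/3 vehicle had 1 female and 1 male library, and a lone library is assumed to vary like the other groups. In the same 21 libraries 41 passed with sex as an additive term. The 4137 genes kept a median of 0.812 of their log2 change with depth class in the model and 0.676 with GC and length trends removed, where 1988 of them passed. Abca1 was 0.60 with depth class in the model (adjusted p = 0.000934) and 0.45 in the higher-depth libraries (adjusted p = 0.113).

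**Figure D4:**
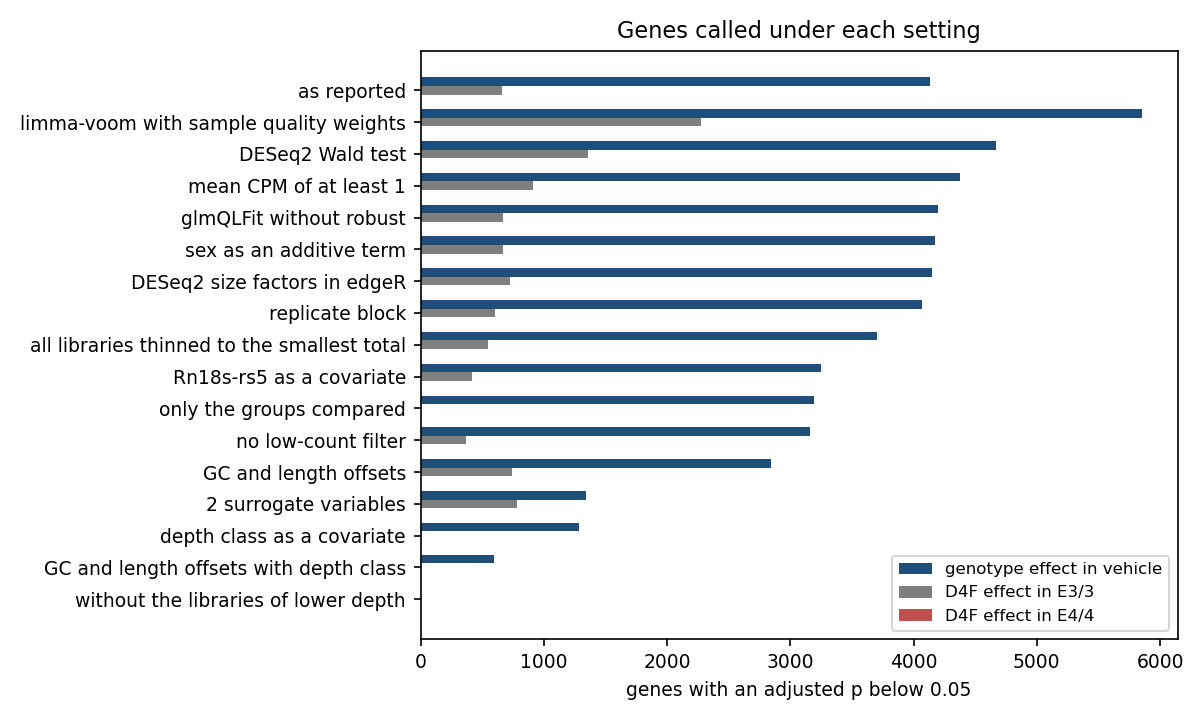
Number of genes past an adjusted p of 0.05 under each setting of the analysis, for genotype in vehicle mice and for D4F against vehicle in E4/4 and in E3/3. The reported settings give 4137, 0 and 659 genes, depth class in the model gives 1286, 0 and 0, and the higher-depth libraries alone give 4, 0 and 0.

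D4F in E4/4 mice was compared with vehicle to ask whether the peptide altered brain expression in APOE4 carriers. Abca1 averaged 35.6 ± 4.78 CPM under vehicle and 32.7 ± 2.65 CPM under D4F (SD, n = 8 each), and its log2 change of −0.12 (SE 0.0771) did not pass (unadjusted p = 0.143, edgeR). Not one of the 20298 genes passed an adjusted p of 0.05 with edgeR, DESeq2 or limma-voom, and 382 had an unadjusted p below 0.05 with edgeR. The smallest unadjusted p among genes with lower values was that of Nagpa, an enzyme that finishes the mannose 6-phosphate tag of lysosomal proteins (−0.33, SE 0.073, edgeR unadjusted p = 9.9e-05, adjusted p = 1), followed by Litaf (−0.27), Enpp6 (−0.43), Fam177a2 (−0.72) and Edn1 (−0.79). On the higher side stood Lars2 (1.005, edgeR unadjusted p = 0.0015, adjusted p = 1), Rn18s-rs5 (1.28), Vwa5b1 (0.61), Zfp951 (0.44) and Cd83 (0.37), where Lars2 contains a stretch related to ribosomal RNA. Of the 12 fixed genes, mouse Apoe had the lowest value (−0.20), and none passed. On simulated data with libraries of these totals, 200 changed genes and the same model, 37% of changes of log2 0.32, 81.5% of 1.5-fold and 97% of 2-fold changes were found in this comparison. The changed genes all had a mean log2 CPM of at least 1, so these shares do not cover genes with fewer counts.

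In E4/4 camera with its preset correlation called 13 lists, 5 higher and 8 lower under D4F. None was called with an estimated correlation or by fry, and no member passed over all genes. Myelin genes were below 0 in all 28 members, including the gap junction gene Gjb1 (−0.24) and Mog (−0.15). The median was −0.13 (camera adjusted p = 3e-13, adjusted p = 0.763 with an estimated correlation), with none past the test adjusted over the list alone. Cholesterol synthesis genes were above 0 in 19 of 20 members, with Mvk at 0.18, Sqle at 0.13 and Fdps at 0.12. The median was 0.05 (camera adjusted p = 0.00149, adjusted p = 0.763 with an estimated correlation), with none past the test adjusted over the list alone. Hypothalamic and neuropeptide genes had a median of 0.47 with 22 of 25 above 0 (camera adjusted p = 0.000179, adjusted p = 0.763 with an estimated correlation) and none past the test adjusted over the list alone. Examples were the hormone precursors Oxt (2.20) and Pomc (1.44) and the hypothalamic factors Sim1 (2.45) and Otp (1.46). The other higher lists were ependyma (median 0.11), glycolysis (0.04) and circadian genes (0.14), and the other lower lists were fibroblasts (−0.20), immediate early genes (−0.17), interferon response (−0.10), antigen presentation (−0.09), pericytes (−0.09), oligodendrocyte precursors (−0.05) and ribosomal proteins (−0.04). Their adjusted p with an estimated correlation ran from 0.763 to 0.970, and adjusted over the list alone only Enpp6, a precursor marker, passed. Leaving out 1 library changed the number of called lists by more than 1.5 times for E4/4 male vehicle replicate 3 (6 lists) and E4/4 female D4F replicate 4 (8 lists).

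In E3/3 mice the same comparison asked what D4F did where APOE4 is absent. Among the genes that passed were 10 of 75 respiratory chain genes, all higher, and a few astrocyte, endothelial and synaptic genes, most of them lower, but no gene list was called with an estimated correlation. Atp5g3, a subunit of the ATP synthase ring, rose from 144 ± 18.6 CPM under vehicle to 205 ± 48.3 CPM under D4F (SD, n = 8 each), a log2 change of 0.51 (SE 0.0922, edgeR adjusted p = 0.0104). Slc1a3, the glutamate transporter of astrocytes, fell from 564 ± 89.3 to 428 ± 52.7 CPM (SD, n = 8 each), a log2 change of −0.40 (edgeR adjusted p = 0.0147). In total 659 genes passed, 367 higher and 292 lower under D4F, with a median absolute log2 change of 0.31, 46 beyond 1.5-fold and 15 beyond 2-fold.

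In the nuclear-encoded respiratory chain list 10 of 75 genes rose and none fell, among them the complex I subunits Ndufc1 (0.51) and Ndufc2 (0.37) and the cytochrome oxidase subunit Cox5a (0.40). The median was 0.09 (camera adjusted p = 7.11e-07, adjusted p = 0.685 with an estimated correlation), with 19 higher adjusted over the list alone. E3/3 male D4F replicate 1 stood apart from the other 3 of its group, with a mitochondrial share of 10.65% (5.71 to 6.74%) and a slope of log counts on gene length of −0.176 (−0.0237 to 0.0657). Atp5g3, Ndufc1, Ndufc2 and Cox5a kept their calls in E3/3 without it. The other 15 lists called by camera were lower under D4F. Astrocyte markers were below 0 in all but 1 of 22 members, and 2 fell, Slc1a3 and the glycolytic Aldoc (−0.23), with 6 lower adjusted over the list alone. The median was −0.15 (camera adjusted p = 9.57e-06, adjusted p = 0.633 with an estimated correlation), and the fry adjusted p was 0.0295. Endothelial genes fell for 5 of 28, including the junction proteins Cdh5 (−0.48) and Pecam1 (−0.32) and the growth factor receptors Eng (−0.40) and Flt1 (−0.33), and 1 rose. The median was −0.13 (camera adjusted p = 0.00101, adjusted p = 0.633 with an estimated correlation), with 9 lower and 1 higher adjusted over the list alone. The unfolded protein list had 3 of 30 lower, Calr (−0.35), Hsp90b1 (−0.22) and Pdia4 (−0.20), with 5 lower adjusted over the list alone. The median was −0.08 (camera adjusted p = 0.00106, adjusted p = 0.633 with an estimated correlation), and the fry adjusted p was 0.0295. In the postsynaptic list 4 of 30 fell, such as Dlgap3 (−0.43) and Dlg4 (−0.32), with 8 lower and 4 higher adjusted over the list alone. The median was −0.11 (camera adjusted p = 0.00333, adjusted p = 0.66 with an estimated correlation). In the presynaptic list 3 of 30 fell, among them Syn1 (−0.39) and Nrxn2 (−0.28), with 4 lower adjusted over the list alone. The median was −0.08 (camera adjusted p = 0.00356, adjusted p = 0.685 with an estimated correlation). Glycolysis had 4 of 24 lower, including Gapdh (−0.31) and Hk1 (−0.29), with 5 lower and 1 higher adjusted over the list alone. The median was −0.07 (camera adjusted p = 0.0121, adjusted p = 0.66 with an estimated correlation).

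Each of the remaining lists had few or no genes past the test. The neighbours of Apoe had 2 lower genes, with Ppp1r37 at −0.34, and a median of −0.09 that was 0.01 once GC and length trends were removed. Insulin signalling had 1, the neurotrophin receptor Ntrk2 (−0.23), and homeostatic microglia had 1, the P-selectin ligand Selplg (−0.33). The interferon response list had 1, the interferon-induced GTPase gene Gbp2 (−0.67), and the related Gbp4, which is not in the list, also fell (−0.93). Fibroblasts (median −0.49), pericytes (−0.28), antigen presentation (−0.15), immediate early genes (−0.13) and oligodendrocyte precursors (−0.10) had none. For all of these the adjusted p with an estimated correlation ran from 0.633 to 0.686. Adjusted over the list alone, 7 neighbours of Apoe, 6 insulin signalling genes, 4 microglial, 3 pericyte, 1 interferon response and 1 antigen presentation gene passed, each lower. Another large decrease was in Gm15542 (−0.89), and other large increases were in Rpl22l1 (0.87), Cyp3a13 (0.76), Arxes2 (0.67), Lars2 (1.04) and the predicted genes Gm28438 (1.63) and Gm6063 (0.95), the last 2 with reads that may be shared with related sequences. Abca1 had a log2 change of 0.21 and Clu of −0.23, and neither passed (edgeR adjusted p = 0.128 and 0.055). The other fixed genes lay between −0.25 (Gfap) and 0.18 (Snap25), and none passed.

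These calls were sensitive to single libraries and to the settings for depth class. No gene passed with depth class in the model (edgeR) or in the higher-depth libraries alone, although the 659 genes kept a median of 0.82 of their log2 change with depth class in the model, 0.284 in the higher-depth libraries and 1.16 in the lower-depth libraries (2 D4F and 6 vehicle, no gene called). With GC and length trends removed 383 of the 659 passed, and of the genes named above Syn1, Nrxn2, Hk1, Aldoc, Eng and Gm28438 did not (adjusted p from 0.0613 for Eng to 0.163 for Nrxn2). Gm28438 and Aldoc kept their calls in 7 of 32 fits that left out 1 library, Syn1 in 12, Hk1 in 14, Lars2 in 15, Nrxn2 in 17, Selplg in 18, and Gapdh and Ntrk2 in 21. Leaving out 1 library moved the count by more than 1.5 times for 12 libraries: without E3/3 male vehicle replicates 1, 2, 3 and 4 it was 99, 279, 1452 and 231, without E3/3 female vehicle replicates 1, 2, 3 and 4 it was 347, 110, 237 and 2188, and without E3/3 female D4F replicates 1, 2, 3 and 4 it was 292, 248, 176 and 1176. In the higher-depth libraries alone the medians of the fibroblast (0.05), interferon response (0.09), microglia (0.06), pericyte (0.02), glycolysis (0.01), antigen presentation (0.01) and Apoe neighbour lists (0.00) were above 0.

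The difference between the D4F effects in E4/4 and E3/3 was tested as an interaction. Abca1 had an interaction of −0.32 (unadjusted p = 0.00625, adjusted p = 0.298), which did not pass. No gene passed with edgeR, where 2113 had an unadjusted p below 0.05 and the smallest adjusted p was 0.257, while DESeq2 called 12 and limma-voom 588. Genes with the smallest p were Ctnnal1 (−0.36), Litaf (−0.45), Pno1 (−0.47), Fam107a (0.58) and Scara3 (0.41). Camera called 11 lists and none with an estimated correlation: myelin (−0.15), respiratory chain (−0.09) and ribosomal proteins (−0.07) were lower, and 8 lists, such as glycolysis (0.12), postsynaptic genes (0.14) and astrocytes (0.09), were higher, with adjusted p from 0.857 to 0.986 with an estimated correlation. Adjusted over the list alone, 4 myelin, 1 ribosomal protein and 1 endothelial gene were lower, and 4 unfolded protein, 3 postsynaptic, 1 glycolysis, 1 astrocyte and 1 endothelial gene were higher. An effect of D4F that passed in E3/3 and not in E4/4 is therefore not shown to differ between the genotypes.

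To ask whether D4F moved expression in E4/4 back towards E3/3, the genotype effect was set against the D4F effect in E4/4, gene by gene. Among the 4137 genes called for genotype, 65.4% changed in the opposite direction under D4F, and the correlation of the changes across genes was −0.22. Both effects use the same E4/4 vehicle mice, which alone produces opposite signs. With neither a genotype nor a D4F effect simulated, 82.3% (range 81.2 to 83.2%) of the 4137 genes with the smallest p were opposite. The correlation was then −0.48. No gene was called for genotype in these simulations, so they do not give the share to be met beside a genotype effect. Each gene was drawn independently, so the simulated range leaves out genes that vary together between mice. When the E4/4 vehicle libraries were divided so that each comparison used its own, the share was 50.8% (range 25.98 to 78.1% over 36 divisions). Genes called in both comparisons numbered 0, since none was called for D4F. Genes are not independent replicates, so these shares carry no p.

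Genotype was compared again among the D4F-treated mice, to ask which differences between E4/4 and E3/3 were present under treatment. The light chain gene Dynlt1b, part of the dynein motor, averaged 2.10 ± 0.403 CPM in E3/3 and 3.92 ± 0.668 CPM in E4/4 (SD, n = 8 each). Its log2 difference was 0.90 (SE 0.155, edgeR adjusted p = 0.0489), and it was the only gene past the test, with 2801 at an unadjusted p below 0.05. Dynlt1b was 0.888 with GC and length trends removed and did not pass (adjusted p = 0.0735), and 0.897 with depth class in the model, where it passed (adjusted p = 0.0236). DESeq2 called 198 genes and limma-voom 332. Without 1 library the count was 0 in 19 of 32 cases and at most 22 (without E3/3 female vehicle replicate 1). Abca1 was 26.03 ± 2.42 CPM in E3/3 and 32.7 ± 2.65 CPM in E4/4 (SD, n = 8 each), a log2 difference of 0.33 (SE 0.0778, edgeR adjusted p = 0.0796). The other fixed genes lay between −0.32 (Snap25) and 0.40 (Gfap). Camera called 23 lists, 14 higher and 9 lower in E4/4, none with an estimated correlation, and fry called 2. Astrocyte markers were above 0 in 21 of 22 members, with Aqp4 at 0.42 and Ednrb at 0.44, and 7 passed adjusted over the list alone. The median was 0.14 (camera adjusted p = 4.70e-08, adjusted p = 0.314 with an estimated correlation), and the fry adjusted p was 0.0249. Fatty acid oxidation had a median of 0.13, with 2 higher adjusted over the list alone (camera adjusted p = 4.76e-05, adjusted p = 0.314 with an estimated correlation, fry adjusted p = 0.0259). Fibroblasts (median 0.48), hypothalamic genes (0.89) and homeostatic microglia (0.16) were higher, and presynaptic genes (−0.15) and blood genes (median −0.13, mean −0.80) were lower, each with an adjusted p near 0.314 with an estimated correlation (0.319 for presynaptic genes). Adjusted over the list alone, 3, 7 and 2 genes were higher, 3 presynaptic genes were lower, and 5 blood genes were lower with 1 higher.

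Treated E4/4 mice were also compared with untreated E3/3 mice, to ask how far apart they stood. Presynaptic genes fell for 15 of 30, with Syn1 at −0.69, and Abca1 was higher (0.54, SE 0.0784, edgeR adjusted p = 6.95e-05). The median was −0.26 (camera adjusted p = 1.05e-08, adjusted p = 0.556 with an estimated correlation), with 16 lower adjusted over the list alone. Hypothalamic genes rose for 8 of 25 and fell for 2, including the hormone and neuropeptide precursors Oxt (4.71), Avp (4.16), Gal (3.29) and Trh (1.55). Members of this list varied together among mice of the same group, with a median pairwise correlation of 0.335 against at most 0.0611 in 200 random lists, and the labels do not name the brain region. The median was 1.49 (camera adjusted p = 0.0041, adjusted p = 0.814 with an estimated correlation), with 12 higher and 2 lower adjusted over the list alone. In all 3927 genes passed, 1937 higher and 1990 lower, 499 beyond 1.5-fold and 169 beyond 2-fold. The largest increases also held Rn7sk (3.73), the insulin receptor substrate Irs4 (2.64), Rn18s-rs5 (2.49), the GABA receptor subunit Gabrq (2.28), Lars2 (2.16) and Aqp1 (2.08), and the largest decreases held Hba-a1 (−2.69), Bc1 (−1.21), Espn (−1.12) and Gipc3 (−1.03). With depth class in the model Bc1 (−0.456, adjusted p = 0.517), Aqp1 (1.32, adjusted p = 0.125), Irs4 (2.57, adjusted p = 0.0627) and Trh (1.44, adjusted p = 0.0617) did not pass. In the higher-depth libraries alone Bc1 was 0.893, Aqp1 2.05, Irs4 4.37 and Trh 2.61. Camera called 12 lists, 4 higher and 8 lower, none with an estimated correlation, 7 with 2 surrogate variables and 15 with depth class in the model. The lower ones were glycolysis (12 of 24 fell), the unfolded protein response (10 of 30), cortical neurons (8 of 24), postsynaptic genes (11 of 30, with 4 higher), Apoe neighbours (9 of 31), blood (5 of 13) and immediate early genes (3 of 26). Their adjusted p ran from 0.514 to 0.814 with an estimated correlation, and 15, 12, 12, 11, 12, 5 and 3 genes were lower adjusted over the list alone. The higher ones were choroid plexus (2 of 23 rose), mitochondrially encoded genes (5 of 15, median 0.20, or −0.07 once GC and length trends were removed) and striatal neurons (none of 21 passed, all above 0). Their adjusted p ran from 0.814 to 0.970 with an estimated correlation, and 1, 6 and 0 genes were higher adjusted over the list alone. No gene passed in the higher-depth libraries alone, 381 passed with Rn18s-rs5 as a covariate, 1612 with depth class in the model, 1967 with 2 surrogate variables and 2223 with GC and length trends removed.

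Male and female vehicle mice differed mainly by genes of the sex chromosomes. The Y-linked Uty (log2 10.4), Eif2s3y (9.91), Kdm5d (9.87), Ddx3y (9.66) and Gm29650 (9.47) were higher in males, and Xist (−10.8) and 3 X-linked genes that escape inactivation, Eif2s3x (−0.66), Kdm6a (−0.47) and Kdm5c (−0.36), were higher in females, which matches the labels. Only 10 genes passed, 6 higher and 4 lower in males, and 747 had an unadjusted p below 0.05. Of 10 lists called by camera, only the list of Y-linked and X-inactivation genes kept its call with an estimated correlation (adjusted p = 0.00167). Its median was −0.35, its mean 3.02 and its test higher in males, with 4 higher and 5 lower adjusted over the list alone. Antigen presentation genes were below 0 in 19 of 20 members. The median was −0.20 (camera adjusted p = 1.86e-08, adjusted p = 0.163 with an estimated correlation), with 3 lower adjusted over the list alone. Without E4/4 male vehicle replicate 4, E3/3 male vehicle replicate 3 or E4/4 female vehicle replicate 1, camera called 4, 6 and 16 lists.

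Within single sexes, each with 4 mice per group, the genotype effect called 2097 genes in females and 806 in males. In females the count was 0 in a fit on only the groups compared, 391 with GC and length trends removed and 780 with depth class in the model. In males it was 0 with 2 surrogate variables and 2 with depth class. In females the smallest adjusted p, 0.000474, was shared by Mir124-2hg (0.57), the host of a neuronal microRNA, the nuclear exporter Xpo1 (0.68) and the chromatin factor Bmi1 (0.73), of which Mir124-2hg did not pass with GC and length trends removed (0.268, adjusted p = 0.0868). In males the leading genes were Abca1 (0.74, SE 0.111, edgeR adjusted p = 0.00285), the neuropeptide precursor Vgf (−0.62) and the ganglioside synthase B4galnt1 (−0.60). With depth class in the model B4galnt1 was −0.474 and did not pass (adjusted p = 0.0798). The interaction of genotype with sex called no gene with edgeR (1090 at an unadjusted p below 0.05), DESeq2 or limma-voom, so the sexes are not shown to differ. Single libraries mattered at this group size: the female count was 1110, 853, 765 and 3288 without E3/3 female vehicle replicates 1, 2, 3 and 4 and 1159, 903 and 1168 without E4/4 female vehicle replicates 2, 3 and 4. The male count was 276, 429 and 59 without E3/3 male vehicle replicates 1, 2 and 4 and 184, 302, 452 and 469 without E4/4 male vehicle replicates 1, 2, 3 and 4. D4F in E4/4 called no gene in females (543 at an unadjusted p below 0.05) or males (366) with edgeR. DESeq2 called 1 and 3, and limma-voom called 0 and 3. Its interaction with sex called none with any of these tools (526 at an unadjusted p below 0.05 with edgeR). D4F in E3/3 called no gene in females with edgeR (2033 at an unadjusted p below 0.05, 176 called with limma-voom and 0 with DESeq2) and 20 in males, 14 higher and 6 lower, led by Atp5g3 (0.68, adjusted p = 0.0398) and the predicted genes Gm10443 (1.01) and Gm7367 (−1.63), and no gene passed in males with depth class in the model or without E3/3 male D4F replicate 1.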

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

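In this part, the tests of fewer counts, of GC content for the genotype and E3/3 D4F calls, of choroid plexus in the tissue piece and of ribosomal RNA left in the libraries were chosen only after the result was seen, as were the fits with depth class, with GC and length offsets, with thinned libraries and without the libraries of lower depth.

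Genotype in vehicle mice gave 4137 genes and D4F in E3/3 gave 659, with no gene list called for either when the correlation between genes was estimated. Both comparisons rest on the E3/3 vehicle mice, 6 of 8 of which have libraries of lower depth. Fewer counts are argued against as the whole cause of the genotype calls, since 3706 genes passed with every library thinned to the smallest total. Once GC and length trends were removed 2845 genes passed for genotype and 738 for D4F in E3/3, among them 1988 of the 4137 and 383 of the 659. These trends are argued against as the whole cause for those shared genes only. The called genes kept a median of 0.676 and 0.767 of their log2 change (median size 0.318 to 0.218 and 0.305 to 0.232, median SE 0.0796 to 0.0703 and 0.0745 to 0.0652), so part of the difference goes with these trends, and for the genes that no longer passed they stay open. Depth class itself stays open: with it in the model the called genes kept a median of 0.812 of their log2 change for genotype (0.770 to 0.846 with each library left out; median size 0.318 to 0.253, median SE 0.0796 to 0.0852) and 0.820 for D4F in E3/3 (0.673 to 0.863), and in the higher-depth libraries alone they kept 0.617 and 0.284, where 2 E3/3 vehicle libraries remain and the median SE is 0.102 and 0.0916. In the lower-depth libraries alone they kept 0.840 (1 E4/4 against 6 E3/3 libraries, 88.0% with the same sign) and 1.16 (2 against 6, 100%), and no gene was called. Within classes the values thus go both ways, from few libraries and on genes chosen for the difference. On a scale from lower-depth E3/3 vehicle (0) to higher-depth E4/4 vehicle (1), held-out E4/4 libraries of lower depth scored 0.741 ± 0.238 (SD, n = 3, of which 2 had D4F) and held-out E3/3 libraries of higher depth 0.541 ± 0.150 (SD, n = 8, of which 6 had D4F), a difference of 0.199 that is smaller than the larger SD. The 2 lower-depth E3/3 D4F libraries scored 0.176 and 0.782, a mean of 0.479. Among higher-depth D4F libraries, E4/4 scored 0.877 (0.728 to 1.14, n = 6) and E3/3 0.547 (0.378 to 0.785, n = 6). At equal depth and treatment the genotypes thus differed in mean, with overlapping ranges. Higher-depth E3/3 vehicle scored 0.525 (n = 2), so the scale also goes with depth. In comparisons with E3/3 vehicle, genotype and treatment therefore cannot be told apart from whatever set the depth of those libraries. Between the D4F arms, each with 2 lower-depth and 6 higher-depth libraries, genotype called 1 gene. Every E4/4 library bears a lower library number than every E3/3 library, in vehicle and in D4F mice. In E3/3 most D4F libraries form a run of numbers that holds no vehicle library, while in E4/4 the numbers of both arms are mixed. What these numbers stand for is not given, so genotype and D4F in E3/3 cannot be told apart from whatever goes with them. The effect of APOE4 itself stays among the open explanations, as untested.

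Choroid plexus genes such as Aqp1 and Cldn1 had a median log2 difference of 0.93 between E4/4 and E3/3 vehicle mice, while the mean of the list per mouse differed by 0.85 with an exact two-sided permutation p of 0.0884 (n = 8 and 8, adjusted p = 0.265 over 6 tests). GC and length trends are argued against, since the median was 0.89 (0.891) once they were removed. A candidate explanation is the amount of choroid plexus that came with each piece of brain: the list's genes rose and fell together among mice of the same group, with a median pairwise correlation of 0.548, against at most 0.0834 in 200 random lists of like abundance. With depth class in the model the median was 0.36, so part of the difference goes with depth. A change in the choroid plexus with APOE4 stays open, as untested. Joint variation within groups was not particular to this list. The median pairwise correlation was 0.4665 for myelin genes (at most 0.1653 in random lists) and 0.4554 for presynaptic genes (at most 0.2793). For fibroblasts it was 0.6786 (at most 0.1075). What each tissue piece held therefore stays open for those lists too, as untested.

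Counts of Rn18s-rs5, an 18S ribosomal RNA gene that selection of messenger RNA should remove, rose under D4F in E3/3 mice, from 362 ± 57.7 to 961 ± 884 CPM (SD, n = 8 each, exact two-sided permutation p = 0.00326, adjusted p = 0.0122 over 15 tests), and in E4/4 mice they were 931 ± 883 and 2298 ± 1209 CPM (adjusted p = 0.0527). In E3/3 the mean rests on male D4F replicates 3 and 4 (2602 and 2146 CPM, against 354 to 614 in the other 6), and the difference of 599 was 365 without replicate 3. EdgeR did not call Rn18s-rs5 for D4F in E3/3 or in E4/4. Depth class is argued against, since the mean log2 change under D4F kept 0.966 of its size with depth class in the model (1.20 and 1.16). Ribosomal RNA left in the libraries is a candidate explanation: among mice of the same group Rn18s-rs5 went with Lars2 (r = 0.963, Spearman 0.921) and with Gm15564 (r = 0.667, Spearman 0.552), which both hold stretches related to ribosomal RNA, with permutation p from 1e-05, the smallest the permutations can give, to 0.00121 (adjusted p from 2e-05 to 0.00121 over 4 tests) and r of 0.944 and 0.564 without the 2 farthest libraries. Gm15564 was chosen after its values were seen. An effect of D4F on ribosomal RNA in the tissue stays open, as untested.

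Single mice stood far from the other 3 of their group in 12 of 152 groups over 19 measures, where the gap passed Dixon's critical value for 4 samples. Chance alone gives about 1 in 20 groups, or 7.6 here. Library size was 35.8 M (mega) counts in E3/3 female vehicle replicate 4 (20.5 to 22.8 in the others), 45.1 in E4/4 male vehicle replicate 1 (31.8 to 34.0) and 17.8 in E4/4 male D4F replicate 2 (39.3 to 40.9). The mitochondrial share was 8.01% in E3/3 female D4F replicate 4 (5.78 to 6.04%). The haemoglobin share was 0.00428% in E4/4 male D4F replicate 3 (0.000552 to 0.001%). The 50 most counted genes took 17.6% in E3/3 male D4F replicate 1 (13.2 to 13.8%). The slope of log counts on GC content was −0.0172 in E4/4 female D4F replicate 2 (−0.00911 to −0.00798). Abca1 was 24.2 CPM in E3/3 male D4F replicate 2 (28.3 to 28.6), Abcg1 was 88.0 CPM in E4/4 male vehicle replicate 1 (70.2 to 72.6), and Lrp1 was 508 CPM in E4/4 female vehicle replicate 1 (408 to 421). In E3/3 female vehicle replicate 1 the astrocyte gene Gfap was 228 CPM (111 to 122) and the synaptic gene Snap25 was 1660 CPM (3030 to 3100).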

How the results depend on the processing

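The settings with depth class, GC and length offsets, Rn18s-rs5, thinned libraries or no lower-depth libraries were added after the result was seen. Counts are of called genes, and the cause was not tested for any changed count except where fewer libraries or genes enter by construction. D4F in E4/4 stayed at 0 genes in all 16 alternatives and without any 1 library. Genotype in vehicle stayed within 1.5 times 4137 under the settings fixed beforehand apart from 2 surrogate variables. For named genes that were called, 1587 values kept direction and call under settings fixed beforehand and 218 lost the call, against 579 and 507 in added ones and 5196 and 628 without 1 library, and 231 values of genes that were not called changed sign.

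DESeq2 size factors gave 0 for genotype under D4F and 35 for D4F in E3/3 males. The DESeq2 Wald test gave 1359 for D4F in E3/3, 12 for the interaction, 198 for genotype under D4F, 1443 for genotype in males, 1 and 3 for D4F in E4/4 females and males, and 406 for D4F in E3/3 males. Limma-voom gave 2271, 588 and 332 for the first 3 of these, 6060 for treated E4/4 against vehicle E3/3, 3652 and 1887 for genotype in females and males, 3 for D4F in E4/4 males, and 176 and 164 for D4F in E3/3 females and males. Without a filter there were 367 for D4F in E3/3, 2 for genotype under D4F, 1361 and 384 for genotype in females and males and 9 for D4F in E3/3 males, and with a mean CPM of at least 1 there were 39 for the last. A fit on only the groups compared gave 0 for D4F in E3/3, 58 for genotype under D4F, 0 for genotype in females, 1 for genotype by sex, 4 for D4F in E4/4 males and 0 for D4F in E3/3 males. Replicate numbers do not pair the mice (mean correlation of same numbers 0.00871, of others −0.00361), and as a block they gave 3 for genotype under D4F and 0 for D4F in E3/3 males. Sex as an additive term gave 15 and fits without robust settings 0 for genotype under D4F. With 2 surrogate variables there were 1344 for genotype, 10 under D4F, 1967 for treated E4/4 against vehicle E3/3, 0 for genotype in males and 55 for D4F in E3/3 males.

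Depth class gave 1286 for genotype, 0 for D4F in E3/3, 27 for genotype under D4F, 1612 for treated E4/4 against vehicle E3/3, 780 and 2 for genotype in females and males and 0 for D4F in E3/3 males. GC and length offsets gave 0 under D4F, 2223 for treated E4/4, 391 for genotype in females and 121 for D4F in E3/3 males; with depth class added they gave 595 for genotype, 4 for D4F in E3/3, 0 under D4F, 596 for treated E4/4, 52 and 3 for genotype in females and males and 0 for D4F in E3/3 males. Without the lower-depth libraries, where fewer mice enter, there were 4 for genotype, 0 for D4F in E3/3, 0 under D4F, 0 for treated E4/4, 0 and 2 for genotype in females and males and 1 for D4F in E3/3 males. The Rn18s-rs5 covariate gave 420 for D4F in E3/3, 2 under D4F, 381 for treated E4/4 and 0 for D4F in E3/3 males, and thinning gave 0 under D4F.

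Camera with an estimated correlation called 0 lists for genotype, D4F in E4/4, D4F in E3/3 and the interaction, and fry called 6, 0, 2 and 0. Depth class, the offsets with depth class and the omission of lower-depth libraries gave 18, 17 and 28 lists for genotype, and that omission gave 8 for D4F in E3/3. It also turned Bc1 to 1.03 and 0.89 in the genotype and treated E4/4 comparisons, Gapdh to 0.029 for D4F in E3/3 and 0.078 for treated E4/4, and Gm28438 to −0.15, and the Rn18s-rs5 covariate turned Prlr to −0.37 for treated E4/4; the cause was not tested. Of the genotype genes, the share opposite under D4F in E4/4 was 100% of 4 genes and 93.6% of the 500 genes with the smallest p without lower-depth libraries, and 50.8% with the vehicle libraries divided. For the 500 genes with the smallest p in all libraries it was 75%, and 91.4% in simulations with no genotype or D4F effect (range 88.8 to 93%). The simulated genes were drawn independently, so this range leaves out genes that vary together. No simulation was run for the higher-depth libraries alone. The correlation was −0.37 and 0.091 and the covariance −0.0443 and 0.00976 without lower-depth libraries and with the division, where the division removes the shared libraries.

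Without 1 library the ranges were 3125 to 4871 for genotype, 99 to 2188 for D4F in E3/3, 0 to 303 for the interaction (303 without E3/3 female vehicle replicate 4), 0 to 22 for genotype under D4F, 2941 to 4694 for treated E4/4, 9 to 13 for sex, 765 to 3288 and 59 to 1047 for genotype in females and males, 0 to 39 for genotype by sex and 0 to 765 for D4F in E3/3 females (39 and 765 without E3/3 female vehicle replicate 4), and 0 to 393 for D4F in E3/3 males. The last was 0 without E3/3 male vehicle replicates 1, 2 or 4, E3/3 male D4F replicates 1 or 4, E4/4 male vehicle replicate 4 or E4/4 male D4F replicate 3; 4, 5 and 11 without E3/3 male D4F 3, E4/4 female D4F 3 and E3/3 female D4F 1; and 35, 48, 55, 174, 239 and 393 without E3/3 female vehicle 1, E3/3 female D4F 4, E4/4 female vehicle 1, E3/3 female vehicle 4, E3/3 male D4F 2 and E3/3 male vehicle 3. Genotype under D4F was 3, 5, 6, 8, 13, 15, 16 and 22 without E3/3 female vehicle 4, E3/3 male D4F 4, E3/3 male vehicle 4, E4/4 female D4F 4, E3/3 male vehicle 3, E3/3 female D4F 2, E4/4 female vehicle 1 and E3/3 female vehicle 1. Lists called for D4F in E4/4 ran from 6 to 16, the opposite share from 58.1 to 78.0%, its correlation from −0.39 (without E4/4 female vehicle 1) to −0.13 and its covariance from −0.0306 to −0.00922. The haemoglobin share differed by −0.00396 to −0.00254 percentage points for genotype, −0.00292 to −0.0021 under D4F and −0.00372 to −0.00229 for treated E4/4, and library size by 8.50 to 12.1 M counts for genotype. On simulated data 82.5%, 81.5% and 80.5% of 1.5-fold changes were found for genotype, D4F in E4/4 and D4F in E3/3.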

Other observations

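The lists, the sexes and the splits described here were planned; the exact tests of list means and the traces of the other sex were chosen only after the result was seen.

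Choroid plexus genes had different medians in the 2 sexes, a difference called by camera with its preset correlation and not with an estimated one. In males they were higher in E4/4 than in E3/3 vehicle mice (median log2 1.97, all 23 members above 0; 1 gene higher, 7 adjusted over the list alone; camera adjusted p = 1.49e-06; adjusted p = 0.578 with an estimated correlation), and in females the median was −0.05 (camera adjusted p = 0.862). The male value rests on E4/4 male vehicle replicates 3 and 4, with a choroid plexus mean of 3.168 and 2.506 log2 CPM against 0.6167 and 0.5654 in replicates 1 and 2, and these libraries also enter the D4F comparison in males. The female value depends on E3/3 female vehicle replicate 4, with a mean of 2.191 against −0.2589 to 0.9481 in the other 3. Under D4F in E4/4 the list was at 1.27 in females and −1.45 in males, where all 23 members were below 0, and the interaction with sex had a median of −2.64 (camera adjusted p = 1.18e-17; adjusted p = 0.411 with an estimated correlation). No gene passed for either of these, with edgeR, over all genes or over the list alone. Markers of ependyma, the ciliated lining of the ventricles, had an interaction of −0.65 (camera adjusted p = 2.87e-08; adjusted p = 0.815 with an estimated correlation).

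Camera with its preset correlation called the ribosomal protein and respiratory chain lists in single sexes, and neither camera with an estimated correlation nor fry did. In E3/3 males under D4F, 2 respiratory chain genes rose over all genes and 31 of 75 adjusted over the list alone (median 0.19; camera adjusted p = 1.24e-15; adjusted p = 0.81 with an estimated correlation), and 1 ribosomal protein gene rose over all genes and 20 of 79 adjusted over the list alone (median 0.18; camera adjusted p = 2.28e-10; adjusted p = 0.87 with an estimated correlation). Of the 4 treated males, replicate 1 stood apart, with a mitochondrial share of 10.65% (5.71 to 6.74% in the others) and a slope of log counts on gene length of −0.176 (−0.0237 to 0.0657). Without it no gene passed in E3/3 males, as with depth class in the model. In females the ribosomal list had a median of −0.11, or 0.016 without the lower-depth libraries (camera adjusted p = 0.000176; adjusted p = 0.8 with an estimated correlation). The genotype by sex interaction of this list was 0.21 with 78 of 79 members above 0, and no gene passed (camera adjusted p = 2.77e-10; adjusted p = 0.553 with an estimated correlation).

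Hypothalamic and neuropeptide genes varied together among mice of the same group, and the labels do not name the brain region. Their mean log2 CPM was higher by 0.61 in E4/4 than in E3/3 vehicle mice (exact two-sided permutation p = 0.0311, adjusted p = 0.186 over 6 tests, n = 8 and 8), by 0.52 in E4/4 mice under D4F (exact permutation p = 0.151, adjusted p = 0.301) and by 0.094 in E3/3 mice under D4F (exact permutation p = 0.705, adjusted p = 0.809), so none passed, and list members of the same group had a median pairwise correlation of 0.335, against at most 0.0611 in 200 random lists of like abundance. Oxt, the oxytocin precursor, averaged 0.101 ± 0.114 CPM in E3/3 vehicle and 2.57 ± 2.82 CPM in E4/4 D4F (SD, n = 8 each).

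The genotype and E3/3 D4F effects also share libraries, those of E3/3 vehicle. Of the 659 genes called for D4F in E3/3, 550 were called for genotype in the same direction, 319 higher and 231 lower, and none in the opposite direction. The correlation of the effects across all genes was 0.57 and 0.53 in simulations with no genotype or D4F effect (covariance 0.0481 and 0.024). With the E3/3 vehicle libraries divided between the comparisons it was 0.18.

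Traces of the other sex were seen: Xist reached 140 counts in an E4/4 male vehicle library, and 4 Y-linked genes together reached 132 counts in an E4/4 female D4F library. Haemoglobin genes took 0.00425 ± 0.00357% of counts in E3/3 vehicle and 0.000788 ± 0.000402% in E4/4 vehicle (SD, n = 8 each; exact two-sided permutation p = 0.00264, adjusted p = 0.0497 over 20 tests), and 0.00348 ± 0.00144% and 0.00103 ± 0.00134% under D4F (exact permutation p = 0.00497, adjusted p = 0.0497).

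Other splits of the same libraries were fitted for each model result. For genotype in vehicle 1 of 100 splits, the real one, gave as many genes (4137, highest other 1092). The same held for treated E4/4 against vehicle E3/3 (1 of 100, 3927 genes, highest other 2689) and genotype in males (1 of 35, 806 genes, highest other 17). No other split tried gave as many in these 3 cases. The real splits also part the libraries by depth class, with 5, 4 and 3 more higher-depth libraries on the E4/4 side. In the highest other splits this difference was −3, 4 and −1. These shares therefore do not tell the labels apart from depth class. The shares were not adjusted over the 15 comparisons, and 35 splits cannot give a share below 1 of 35. The male count was also 2 with depth class in the model and 59 without E3/3 male vehicle replicate 4. For D4F in E3/3, 3 of 100 splits gave as many (659, highest other 1020; 99 without E3/3 male vehicle replicate 1). This share is under 0.05, but both other splits part the libraries by depth class, with 6 more higher-depth libraries on 1 side, and no gene passed with depth class in the model. Fewer than 0.05 of the splits gave as many in 3 further cases, but leaving out 1 library took each count to or below the highest other. Excluding chance there would rest on single libraries. These were genotype under D4F (1 of 100; 1, highest other 0; 0 in 19 of 32 fits without 1 library), genotype in females (1 of 35; 2097, highest other 1901; 765 without E3/3 female vehicle replicate 3) and D4F in E3/3 males (1 of 35; 20, highest other 1; 0 without any 1 of the 7 libraries named above). In fits on only the groups compared D4F in E3/3, genotype in females and D4F in E3/3 males gave 0, and with 2 surrogate variables genotype in males gave 0. By the number of genes chance cannot be excluded for sex (6 of 100; 10, highest other 335), but this says nothing of Uty, Eif2s3y, Kdm5d, Ddx3y, Gm29650 and Xist, which passed in 16 of 16 settings and in all 32 fits without 1 library. Where the real count is 0 every split gives at least as many, so the splits decide nothing for D4F in E4/4 (100 of 100; 0, highest other 31), the interaction (100 of 100; 0, highest other 1), genotype by sex (100 of 100; 0, highest other 2038), D4F by sex in E4/4 (100 of 100; 0, highest other 1), and D4F in E4/4 females (35 of 35; 0, highest other 0), E4/4 males (35 of 35; 0, highest other 1) and E3/3 females (35 of 35; 0, highest other 1632). What the splits that call 335, 2038 or 1632 genes line up with, where the real ones call 10, 0 and 0, was not tested. Between their sides the number of higher-depth libraries differed by 3, −5 and −4. For genotype by sex the splits exchange genotype labels within each sex, so a split can take up the genotype effect itself.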
